A study of Mus musculus with 30 samples.

How the data were processed

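The data are poly-A selected RNA libraries from 30 PyMT-induced mammary tumours, 1 per animal, made with fragmentation, adapter ligation and size selection on a gel, per the labels' protocols. The authors deposited 1 table of RPKM values (reads scaled to transcript length and library size), with a row for each of 27902 RefSeq transcripts and a column for each animal. The unit was inferred from the values, since no source used here names it: low values of short transcripts multiplied by transcript length fell on multiples of a step that differed between columns. CASAVA 1.7.0 is named per the submitters' processing notes; the aligner settings, genome build and annotation release are not given in the sources used here. All 30 columns were used.

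Transcripts were named by their accessions with a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of genes (26486 transcripts), and with GENCODE vM21 (158). The remaining 1258 transcripts, with 1.94% of the summed RPKM, were left out. For the 3303 genes with more than 1 transcript the transcript with the highest mean was used, because transcripts of a gene share reads. Small RNA genes (686 transcripts) were left out, since poly-A selection does not capture them evenly. This gave 20855 genes, of which 389 had values identical to those of another gene. These choices were made after the file had been seen.

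Depth was recovered from transcripts of 150 to 2500 bases as the step that best aligned low values; between 45.0 and 68.5% of these values lay within 0.12 of a whole number of reads, against 24% by chance. The share was too low to rebuild counts, so no count test was run. The libraries fell into 16 shallow and 14 deep ones at the largest gap in depth. The class was treated as a technical batch; the labels do not name it, and it was defined after the file had been seen.

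Values were analysed as log2(RPKM + 1), which understates changes of low genes, for genes with a mean of at least 1 RPKM over the 30 tumours. Slopes and SDs are on that scale. The score of a list was the mean of its members' standardised values, and each list score was divided by its SD. Each gene was regressed on the proliferation, stroma matrix, T cell and milk scores and on the insert size given in the labels, with limma 3.58.1 (empirical Bayes with trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A member of a list was tested against the score of the other members, and counts of genes leave members out. Because each animal gave 1 library, errors and p-values measure the spread between animals with technical variation included. The share of tumour cells in each piece is not given in the labels.

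There were 21 lists: proliferation, T cell, B cell, macrophage, MHC class II, interferon response, stroma matrix, mesenchymal regulators, endothelial, luminal epithelial, milk secretory, basal and myoepithelial, adipocyte, skeletal muscle, keratinised epithelium, erythroid, hypoxia, immediate early, oxidative phosphorylation, ribosomal protein and metastasis modifiers. Cd68, Col6a3, Flg and Hbb-b1 were not analysed here. The lists, tests, thresholds, the alternatives named first below and the rule for named genes were fixed before the data were examined. For each score that rule took the 10 genes outside the list with the smallest adjusted p in each direction and the 3 most abundant members. For insert size it took 5 genes in each direction, for variable genes the 10 with the largest SD, and for 2-component genes the 12 with the largest likelihood ratio. For each list it took the members with the highest mean and the largest and smallest SD, of which the text gives a selection. Tpx2, Sipa1, Rrp1b and Xist were among the genes taken in every case, and predicted genes without a name were passed over. Some genes that the rule took are not reported here.

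Pairs of lists were compared with Pearson's r and Spearman's rho and 100000 permutations, again without the 2 tumours farthest from the median of the first score, and within each depth class. Coherence of a list was set against 10000 random lists matched on expression in 10 groups. The 2-component test compared mixtures of 2 normal distributions and of 1 with equal variances, against 10000 simulated samples. Proximity was tested by permuting gene positions among the called genes. These used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; plots used matplotlib 3.10.9.

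The methods were tested on simulated data for 13615 genes. For insert size, 8% of genes with a simulated slope of 0.1 log2 units per SD were recovered, 64% at 0.25 and 96% at 0.5, with 2.94% false calls. For 2-component genes, 10% were recovered at a separation of 4 SD, 68% at 5 and 96% at 6, with 1.14% false calls. For the comparison of depth classes, 66% were recovered at a log2 difference of 0.5 and 96% at 1, with 4.96% false calls. In 190 simulated pairs of scores, the linked pair (r of 0.7) passed and 0 others did. Apart from the effects added, simulated genes and scores were independent and normally distributed, whereas the real genes are correlated with each other. The shares recovered and the shares of false calls therefore need not hold for the real data.

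The alternatives fixed in advance were a pseudocount of 0.1, no filter beyond a mean above 0, a mean of at least 5 RPKM, quantile normalization, insert size or the library total as a covariate, a score from ranks, Spearman's rho, leaving out the 2 farthest tumours or each tumour in turn, a spread from the median absolute deviation, other shares of the smaller component and other distances. Added after the data had been seen were the depth class as a covariate or as a subset, the median over a gene's transcripts, small RNA genes kept, residuals after insert size for 2-component genes, leaving out each tumour for variable genes and the comparison of depth classes. Marker lists for genes that escape X inactivation, Y-linked genes, lymph node stroma and salivary gland were also added then.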

Results

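The series holds gene expression in mammary tumours of 30 backcross mice. The polyoma middle T antigen (PyMT) is a viral oncogene that drives mammary tumours in mice. Mice from a cross of the wild-derived MOLF strain with PyMT mice were crossed again to FVB, so that each animal carried its own mixture of MOLF and FVB segments. Poly-A selected RNA of 1 tumour per animal was sequenced. The labels place all 30 tumours in 1 group and give no treatment, stage or genotype, so the comparisons below are relations across tumours, with n = 30 unless another number is given. Animals are named by the number in their labels. The deposited values were in RPKM, which scales reads to transcript length and library size, for 27902 RefSeq transcripts, from which 20855 genes were named and 13615 with a mean of at least 1 RPKM were tested. Read depth, recovered from the steps between low values, fell into 2 ranges. There were 16 shallow libraries with 42.7 to 62.0 M reads and 14 deep libraries with 117.1 to 196.9 M reads. Correlations between tumours over all genes ranged from 0.936 to 0.991 (median 0.978), and no pair of libraries was identical.

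The genes that differed most between tumours were milk proteins and skeletal muscle genes. The 10 with the largest SD of log2(RPKM + 1) were the caseins Csn2 (SD 3.52), Csn1s2a (3.32) and Csn1s1 (2.89), the muscle genes Acta1 (3.48), Myh4 (3.23), Tnnt3 (2.94) and Pvalb (2.86), and the secreted proteins Glycam1 (3.0), Scgb1b27 (2.93) and Pip (2.87). Csn2 ranged from 1.78 RPKM in its lowest tumour to 17438 RPKM in the tumour of animal 3540, with a median of 111 RPKM. Acta1, the skeletal muscle actin, ranged from 0.551 RPKM in animal 4036 to 4653 RPKM in animal 3273. In all, 238 genes had an SD of at least 1, against a median SD of 0.272 over all tested genes. They included 14 of 14 skeletal muscle genes, 10 of 12 adipocyte genes, 8 of 10 milk genes, 3 of 4 keratinised epithelium genes and 3 of 5 erythroid genes. None of the 33 proliferation, 21 stroma matrix, 13 endothelial, 12 luminal epithelial or 12 ribosomal protein genes reached it. The count is a value without a test. It was 494 with a pseudocount of 0.1 and 155 with a spread based on the median absolute deviation.

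Most of the gene lists varied as units. The mean pairwise correlation of members was highest for skeletal muscle (0.951), adipocyte (0.911) and keratinised epithelium (0.91), followed by MHC class II (0.826), interferon response (0.793), stroma matrix (0.776), proliferation (0.746) and endothelial genes (0.732). It was 0.654 for T cell, 0.631 for B cell, 0.627 for milk, 0.609 for ribosomal protein, 0.559 for erythroid, 0.465 for macrophage, 0.464 for hypoxia and 0.444 for oxidative phosphorylation genes. Mesenchymal regulators had 0.435, immediate early genes 0.345 and basal and myoepithelial genes 0.342. These 19 of 21 lists exceeded random lists of the same size and expression (adjusted p of at most 0.000221, Benjamini-Hochberg, one-sided, from 10000 random lists each, in which 0.0001 is the smallest unadjusted p possible). The luminal epithelial list (0.067, adjusted p = 0.376) and the metastasis modifier list (0.037, adjusted p = 0.376) did not. Within the luminal list, Krt18 averaged 521 ± 112 RPKM (SD) and Epcam 442 ± 74.7 RPKM, while Krt19 ranged from 24.4 to 481 RPKM. Cadm1 was the most variable metastasis modifier (SD 0.56 on the log2 scale) and Luc7l the most abundant (42.5 ± 11.5 RPKM).

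**Figure D1:**
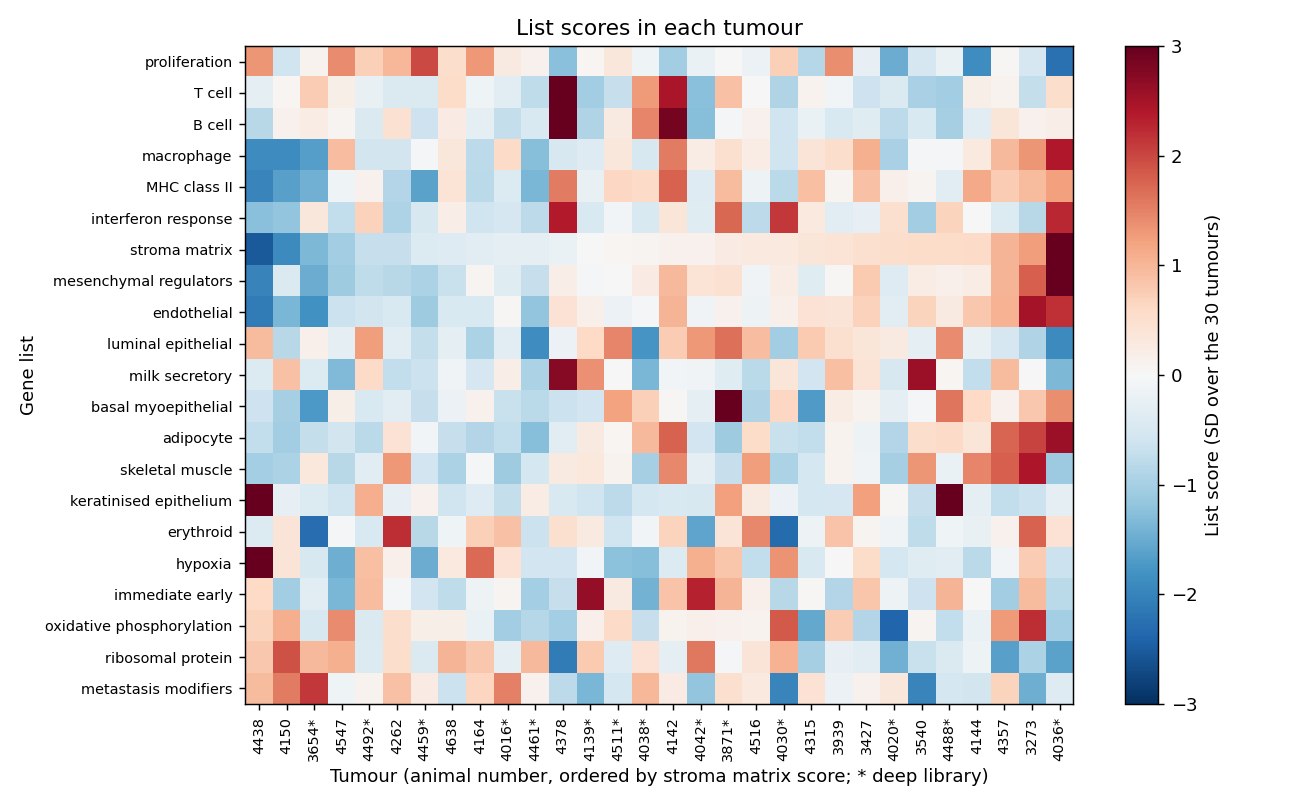
Score of each of the 21 gene lists (rows) in each of the 30 tumours (columns, named by animal number and ordered by stroma matrix score), in SD over the tumours; an asterisk marks the 14 deep libraries and colours saturate at 3 SD. The tumour of animal 4036 had the highest stroma matrix score (3.14) and the lowest proliferation score (-2.24), and animal 4378 the highest T cell (3.31), B cell (3.28) and milk (2.74) scores.

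Tumours with a higher proliferation score had lower levels of most stroma matrix and MHC class II genes tested. Among the 10 rising genes outside the list with the smallest p were Lmnb1 (0.34 ± 0.03 log2 units per SD of the score, SE), a nuclear lamin, the spindle proteins Tacc3 (0.36 ± 0.03), Kif4 (0.33 ± 0.03), Dlgap5 (0.29 ± 0.03) and Ckap2l (0.27 ± 0.02), the replication factors Mcm10 (0.28 ± 0.02) and Mcm7 (0.26 ± 0.02), Cdca2 (0.27 ± 0.02) and the exonuclease Exo1 (0.29 ± 0.03). The falling genes were led by Traf1, a signalling adaptor of tumour necrosis factor receptors (-0.61 ± 0.09), Plce1 (-0.25 ± 0.04), the insulin receptor substrate Irs1 (-0.45 ± 0.07), the natriuretic peptide receptor Npr2 (-0.42 ± 0.07) and Rdh12 (-0.37 ± 0.06). Postn (-0.52 ± 0.09), a matrix protein that is also in the stroma list, Lsp1 (-0.42 ± 0.07), Iqsec2 (-0.22 ± 0.04), Gabbr1 (-0.28 ± 0.05) and Csdc2 (-0.50 ± 0.09) followed.

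In limma with Benjamini-Hochberg adjustment, 2084 genes outside the list passed an adjusted p of 0.05, of which 1201 rose and 883 fell. The named genes above had adjusted p between 2.6e-11 and 0.000219. All 33 members rose when each was set against the other members, over all genes and when adjusted over the list alone, among them Ube2c (0.29 ± 0.07), Rrm2 (0.36 ± 0.06) and Cdc20 (0.35 ± 0.03). Of the other lists, 15 of 21 stroma matrix genes fell (19 changed when adjusted over the list alone), 6 of 7 MHC class II genes fell (7 over the list alone) and 6 of 13 endothelial genes fell (12 over the list alone). No interferon response gene passed over all genes in limma, while 13 of 20 had an unadjusted p under 0.05 and 11 passed when adjusted over the list alone. The 2 list scores did not pass as a pair (r = -0.398, permutation p = 0.0302, adjusted p = 0.132; rho = -0.321, p = 0.0849, adjusted p = 0.274), with r = -0.265 without animal 4036. Among ribosomal protein genes 3 of 12 rose (7 over the list alone). Without animals 4036 and 4459, the tumours farthest from the median score, 924 genes passed (672 rising, 252 falling), and without animal 4036 alone 1200 passed (823 rising, 377 falling). With a mean of at least 5 RPKM, 1129 rose and 521 fell. Within the deep libraries 250 genes passed (186 rising, 64 falling) and within the shallow libraries 447 (365 rising, 82 falling).

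Tumours with a higher stroma score had higher levels of the adipocyte and endothelial genes and of most MHC class II genes, and lower levels of most proliferation genes. Rising genes outside the list were led by the secreted glycoprotein Fstl1 (0.71 ± 0.04 log2 units per SD, SE), the collagen Col14a1 (0.75 ± 0.05), Ccdc80 (0.67 ± 0.05), Srpx (0.51 ± 0.04) and Serpinf1 (0.60 ± 0.05). The procollagen protease Adamts2 (0.50 ± 0.04), the basement membrane protein Nid1 (0.69 ± 0.06), the proteoglycans Podn (0.59 ± 0.05) and Prelp (0.74 ± 0.07) and the collagen receptor Antxr1 (0.47 ± 0.04) followed. The 10 falling genes with the smallest p were the nucleolar proteins Nop56 (-0.22 ± 0.03), Nop58 (-0.25 ± 0.04), Gnl3 (-0.22 ± 0.03) and Rpf1 (-0.19 ± 0.03), the microtubule regulator Stmn1 (-0.29 ± 0.04), the chromatin protein Hmgb2 (-0.30 ± 0.05), Ccdc58 (-0.28 ± 0.04), Nudt5 (-0.19 ± 0.03), Uchl3 (-0.23 ± 0.04) and Cdc123 (-0.14 ± 0.02).

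In limma with Benjamini-Hochberg adjustment, 2841 genes outside the stroma list passed, 1369 rising and 1472 falling. The split moved with the filter, to 778 rising and 1326 falling with a mean of at least 5 RPKM and to 1807 rising and 1485 falling without a filter. All 21 members rose, over all genes and when adjusted over the list alone, including Col1a1 (0.65 ± 0.06), Col3a1 (0.92 ± 0.04) and Sparc (0.57 ± 0.04). All 12 adipocyte genes (median 0.92 log2 units per SD) and all 13 endothelial genes (median 0.31) rose, with the same counts when adjusted over the list alone. So did 10 of 18 macrophage genes (15 over the list alone), 6 of 7 MHC class II genes (7 over the list alone), 6 of 10 basal and myoepithelial genes (6 over the list alone), 5 of 20 interferon response genes (7 over the list alone) and 4 of 6 mesenchymal regulators (5 over the list alone). The proliferation list fell in 20 of 33 genes (29 over the list alone), the ribosomal protein list in 6 of 12 (10 over the list alone) and the hypoxia list in 3 of 16 (3 over the list alone). Col1a1 reached 1718 RPKM in animal 4036, against a median of 332 RPKM. Within the deep libraries 660 genes passed (574 rising, 86 falling) and within the shallow libraries 1497 (803 rising, 694 falling).

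Tumours with a higher T cell score had higher levels of most B cell genes tested. The rising genes were led by the B cell receptor subunits Cd79b (0.78 ± 0.06 log2 units per SD, SE) and Cd79a (0.82 ± 0.08), the B cell surface proteins Fcer2a (0.63 ± 0.05) and Cd22 (0.62 ± 0.06), the lymphocyte GTPase Gimap3 (0.76 ± 0.07) and the chemokine Ccl5 (0.62 ± 0.06). The cytokine receptor Il21r (0.42 ± 0.04), the integrin Itgb7 (0.51 ± 0.05), the class II chaperone subunit H2-Oa (0.40 ± 0.04) and Rasal3 (0.42 ± 0.04) completed the 10. Falling genes that passed were Rasl11b (-0.28 ± 0.06), Sac3d1 (-0.19 ± 0.05), Alad (-0.15 ± 0.04), Pabpc4 (-0.16 ± 0.04) and Trim28 (-0.17 ± 0.04). The other 5 of the 10 lowest, Zfp771 (-0.22 ± 0.06), Slc25a10 (-0.13 ± 0.04), Rdh13 (-0.15 ± 0.04), H2ax (-0.23 ± 0.07) and Kctd5 (-0.10 ± 0.03), did not pass (adjusted p from 0.0529 to 0.0638, limma).

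In limma with Benjamini-Hochberg adjustment, 202 genes outside the T cell list passed, 197 rising and 5 falling. Of 18 listed T cell genes only 8 had a mean of at least 1 RPKM, and these 8 rose, over all genes and when adjusted over the list alone, including Lck (0.27 ± 0.06), Cd4 (0.29 ± 0.07) and Cd3g (0.67 ± 0.06). Of the B cell list 4 of 5 rose (5 over the list alone) and of the MHC class II list 1 of 7 (4 over the list alone). No interferon response gene passed over all genes in limma, while 15 of 20 had an unadjusted p under 0.05 and 13 passed when adjusted over the list alone. The 2 list scores did not pass as a pair (r = 0.441, permutation p = 0.015, adjusted p = 0.077; rho = 0.314, p = 0.0904, adjusted p = 0.279), with r = 0.228 without animal 4378. Without animals 4378 (score 3.31 SD) and 4142, the farthest from the median, 306 genes passed, 255 of them rising. The count was 100 after quantile normalization, 412 with a score made from ranks, and 646 with no filter on low genes. Within the deep libraries 20 genes passed and within the shallow libraries 112.

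**Figure D2:**
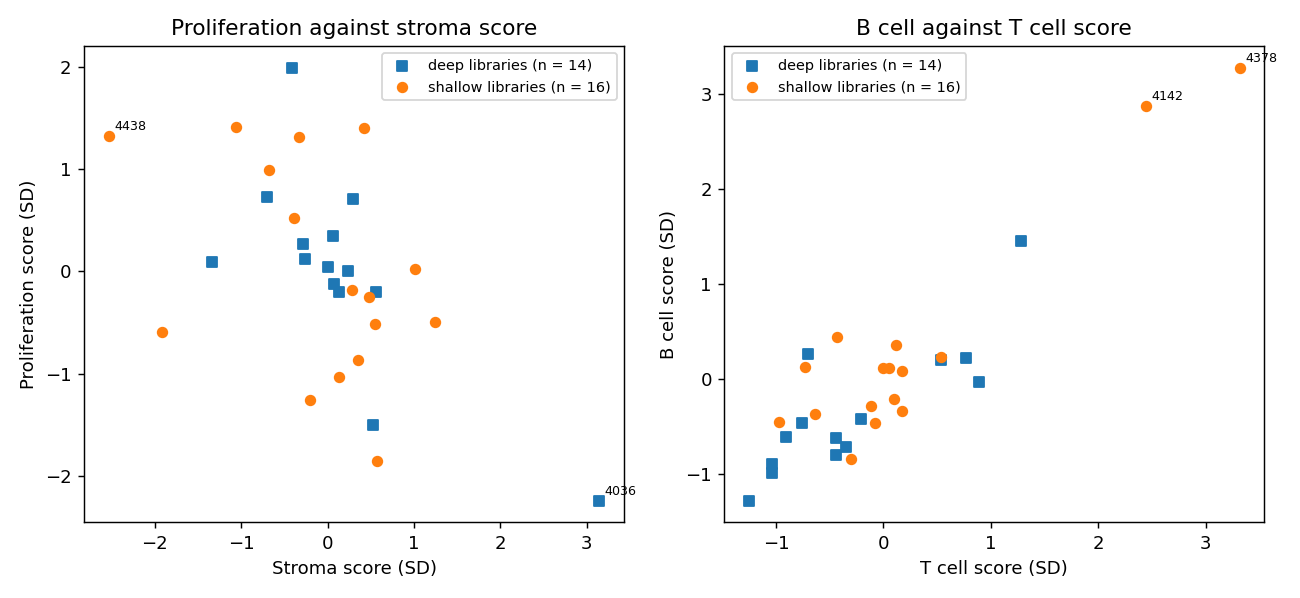
Scores of single tumours in SD over the 30 tumours, with squares for the 14 deep and circles for the 16 shallow libraries; the left panel sets the proliferation score (y) against the stroma score (x), the right panel the B cell score (y) against the T cell score (x). Proliferation fell with stroma (r = -0.553) and animal 4036 lies at the far end; T and B cell scores rose together (r = 0.90), with animals 4378 and 4142 highest in both.

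Outside the list, the genes with the smallest p among those rising with the milk score were Btn2a2 (0.54 ± 0.06 log2 units per SD, SE), Olah (1.0 ± 0.14), a thioesterase that releases medium-chain fatty acids, the chaperone Clu (0.40 ± 0.06), Elf5 (0.26 ± 0.04), a transcription factor of milk-producing cells that is also in the luminal list, and the sterol synthesis enzyme Msmo1 (0.24 ± 0.04). The amino acid oxidase Lao1 (1.08 ± 0.17), Rab7b (0.26 ± 0.04), Prr27 (0.68 ± 0.11), the milk protein lactotransferrin Ltf (0.71 ± 0.12) and the cytokine receptor Cntfr (0.66 ± 0.12) followed. Falling genes included the RNA-binding protein Cirbp (-0.28 ± 0.05), Calcoco1 (-0.23 ± 0.04), the membrane protein Prom2 (-0.57 ± 0.10), Tmem237 (-0.18 ± 0.03), the deacetylase Hdac11 (-0.28 ± 0.05), Snx33 (-0.17 ± 0.03), Dcaf8 (-0.13 ± 0.03), Smg6 (-0.18 ± 0.04) and Bnipl (-0.28 ± 0.06).

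In limma with Benjamini-Hochberg adjustment, 151 genes outside the milk list passed, 65 rising and 86 falling; after quantile normalization 94 rose and 39 fell. Of the 10 members 9 rose over all genes and 10 when adjusted over the list alone, including Csn3 (0.37 ± 0.08), Csn1s1 (2.50 ± 0.26) and Csn2 (3.10 ± 0.30). No other list had more than 1 gene passing. The count depended on single tumours. It was 76 without animal 4378, 81 without animal 4038, 93 without animal 3540 and 326 without animal 4150, and 51 without animals 4378 and 3540 together. Within the deep libraries 4 genes passed and within the shallow libraries 26.

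The mean insert size, the only technical variable that the labels give (its unit is not given), was related to few genes in limma with Benjamini-Hochberg adjustment. Macrod1 (0.31 ± 0.05 log2 units per SD, SE) and the muscle phosphorylase kinase subunit Phka1 (0.37 ± 0.07) rose, and the mitochondrial complex I gene Ndufs5 (-0.29 ± 0.05) fell (adjusted p = 0.00872 for each). The pseudogenes Hnrnpa1l2-ps2 (-0.32 ± 0.06) and Ndufs5-ps (-0.29 ± 0.05) fell as well; reads of Ndufs5 and its pseudogene may have been shared, so their separate values are uncertain. The next genes, Phkg1 (0.35 ± 0.07), Milr1 (0.33 ± 0.07), Asb5 (0.47 ± 0.10), H1f0 (-0.20 ± 0.04) and Tmem107 (-0.18 ± 0.04), did not pass (adjusted p from 0.052 to 0.0612). No skeletal muscle gene passed over all genes, while 14 of 14 had an unadjusted p under 0.05 and 14 passed when adjusted over the list alone, with a median of 1.35 log2 units per SD. These genes vary together (mean pairwise r of 0.951), so the 14 are not separate observations. Adjustment over the list alone does not cover the other lists. The muscle score also differed by -0.93 SD between the deep libraries, which had shorter inserts, and the shallow ones (permutation p = 0.0081, adjusted p = 0.085 over the 21 lists), and animal 3273 had the largest insert size (275.7) and the highest muscle score (2.43 SD). Insert size was lower in the 14 deep libraries (233 ± 14.7, SD) than in the 16 shallow ones (261 ± 12.3), so that the 2 could only be partly separated, and 468 genes passed with the depth class as a covariate (67 rising, 401 falling). The direction depended on the tumours included: without animals 3871 and 3654 together 134 genes passed, all rising. The count of 5 also moved to 1 without animal 3871, 8 without animal 4459, 9 without animal 4150, 12 without animal 4164, 76 without animal 4638 (61 rising, 15 falling), 83 without animal 3654 (78 rising, 5 falling) and 113 without animal 4438 (85 rising, 28 falling). Within the deep libraries 16 genes passed (1 rising, 15 falling) and within the shallow libraries 2, both falling.

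Scores of the stroma matrix, mesenchymal, endothelial, adipocyte, macrophage and MHC class II lists rose and fell together by r, and ribosomal protein scores ran against them by r, except that macrophage narrowly missed the threshold (r = -0.482, permutation p = 0.00769, adjusted p = 0.0505; rho = -0.404, p = 0.0283, adjusted p = 0.135). The proliferation score ran against stroma matrix, mesenchymal, endothelial and MHC class II scores. The T cell and B cell scores rose with each other. With MHC class II they passed for r (0.482, permutation p = 0.00606, adjusted p = 0.0424, and 0.523, p = 0.00224, adjusted p = 0.0188) but not for rho (0.438, p = 0.0166, adjusted p = 0.0997, and 0.479, p = 0.00825, adjusted p = 0.0577), and r was 0.24 and 0.3 without animals 4378 and 4142. They did not pass with stroma matrix (r = -0.034 and 0.031) or macrophage scores (0.124 and 0.185). Of 210 pairs of lists, 31 were correlated (permutation test with 100000 resamples, two-sided, Benjamini-Hochberg over the 210 pairs), 21 positively and 10 negatively; 24 of them also passed with Spearman's rho. Those that did not included mesenchymal regulators with ribosomal protein (r = -0.487, permutation p = 0.00581, adjusted p = 0.0421; rho = -0.377, p = 0.0407, adjusted p = 0.178; -0.378 without animals 4036 and 4438), adipocyte with ribosomal protein (r = -0.48, p = 0.00687, adjusted p = 0.0465; rho = -0.405, p = 0.0269, adjusted p = 0.135; -0.355 without animals 4036 and 3273), MHC class II with adipocyte (r = 0.516, p = 0.00377, adjusted p = 0.0303; rho = 0.434, p = 0.0178, adjusted p = 0.1) and endothelial with metastasis modifier scores (r = -0.51, p = 0.00389, adjusted p = 0.0303; rho = -0.447, p = 0.0133, adjusted p = 0.0848). The T cell and B cell scores had the highest r (0.90, rho 0.705, 0.717 without animals 4378 and 4142, 0.829 within the deep and 0.923 within the shallow libraries). Their permutation p for r was 1e-05, the smallest possible, with an adjusted p of 0.000233, and that for rho was 2e-05 (adjusted p = 0.0007). Mesenchymal regulators and endothelial genes had r = 0.898 (rho 0.853, 0.883 without the 2 farthest tumours, 0.943 deep, 0.913 shallow), stroma matrix and mesenchymal regulators 0.883 (rho 0.785, 0.754, 0.956, 0.833) and stroma matrix and endothelial genes 0.873 (rho 0.852, 0.827, 0.913, 0.921). For these 3 pairs the permutation p was 1e-05 for r and for rho, the smallest possible, with adjusted p of 0.000233 and 0.0007. Proliferation fell with MHC class II (r = -0.607, permutation p = 0.00038, adjusted p = 0.00399; rho = -0.604, p = 0.00044, adjusted p = 0.00727; -0.521 without animals 4036 and 4459, -0.598 deep, -0.634 shallow). It also fell with stroma matrix (r = -0.553, permutation p = 0.00161, adjusted p = 0.0147; rho = -0.596, p = 0.00065, adjusted p = 0.00853; -0.421 without animals 4036 and 4459, -0.73 deep, -0.421 shallow). Ribosomal protein and MHC class II scores had r = -0.643 (permutation p = 0.00012, adjusted p = 0.00148; rho = -0.596, p = 0.00071, adjusted p = 0.00877; -0.585 without animals 4438 and 4150, -0.506 deep, -0.735 shallow). The sign of r differed between the depth classes for 1 of the 31 pairs, adipocyte and skeletal muscle (r = 0.568, permutation p = 0.00127, adjusted p = 0.0121; rho = 0.484, p = 0.00748, adjusted p = 0.0542), with -0.153 in the deep and 0.907 in the shallow libraries, so this relation did not hold within both.

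In a backcross, each animal has 1 of 2 genotypes at each locus, so genes were tested for values that fall into 2 components over the tumours; the components were not used as groups. Ms4a8a (gap between the component means 1.77 on the log2(RPKM + 1) scale, 33.3% of tumours in the smaller component), Ceacam2 (2.45, 43.3%), the interferon-induced membrane protein Ifitm2 (2.46, 50%), Slc37a1 (1.24, 30.0%) and the ribosomal protein Rpl29 (2.26, 36.7%) had the largest likelihood ratios. Ifitm2 ranged from 88.5 to 1497 RPKM and Rpl29 from 48.5 to 514 RPKM. Next came the zinc finger gene Zfp934 (1.06, 46.7%), Pced1b (2.34, 36.4%), Cd300ld4 and Cd300ld5 (1.76, 43.3%), the class I gene H2-M2 (2.52, 30.1%), the arylsulfatase Arsa (1.13, 36.7%) and the glyoxalase Glo1 (0.78, 30.4%). Cd300ld4 and Cd300ld5 had identical values in every tumour, so that they are not separate measurements, although both enter the counts. In all, 62 genes passed (likelihood ratio against 10000 simulated normal samples, Benjamini-Hochberg adjusted p of 0.05, smaller component of at least 25%), with a median gap of 1.1. In 4 of the 62 the absolute r with the depth class exceeded 0.5: Pde4c (-0.90), Gm3336 (-0.90), Rgs14 (-0.79) and Tbxa2r (-0.74), so that their components largely follow the libraries. Each of the 12 named genes had an adjusted p of 0.006, from the smallest p the simulation allows. The count was 26 after removal of the depth class and 21 after removal of insert size, of which 25 and 19 were among the 62. With a mean of at least 5 RPKM it was 25.

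**Figure D3:**
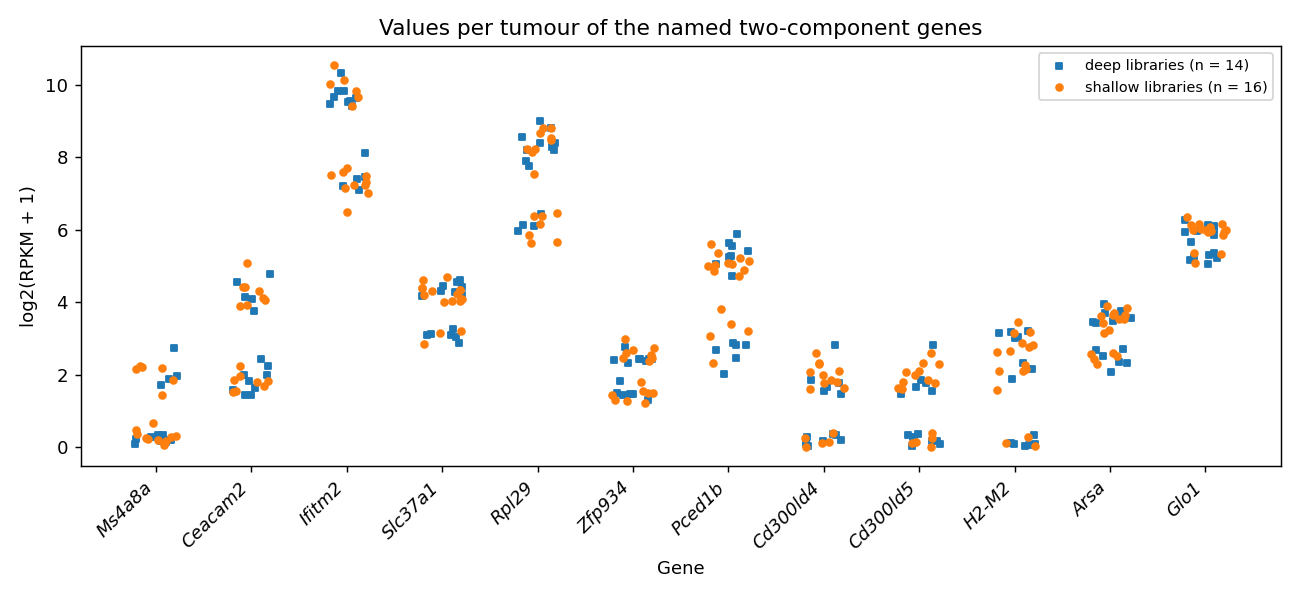
Values of the 12 named 2-component genes in each of the 30 tumours as log2(RPKM + 1), with squares for the 14 deep and circles for the 16 shallow libraries; points are spread sideways at random for display. Both kinds of library occur in the upper and the lower cloud of each gene, as for Ifitm2 with a gap of 2.46.

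Genes of this kind that lie near each other on a chromosome were correlated over the tumours. The mean absolute r was 0.365 for the 81 pairs 0.1 to 20 Mb apart and 0.170 for the 1751 pairs on different chromosomes (difference 0.194, one-sided permutation of gene positions, p = 0.0001, the smallest possible with 10000 resamples). It was 0.412 at 1 to 5 Mb (20 pairs), 0.435 at 5 to 10 Mb (20 pairs), 0.289 at 10 to 20 Mb (34 pairs), 0.265 at 20 to 40 Mb (23 pairs), 0.136 at 40 to 80 Mb (16 pairs) and 0.233 at 80 to 200 Mb (12 pairs). Over all 13605 tested genes placed on the autosomes or the X chromosome, the difference was 0.0138 (p = 0.0099, the smallest possible with 100 resamples). Among the named genes, Slc37a1, H2-M2 and Glo1 share a chromosome, as do Pced1b and Arsa, and Ceacam2 and Ifitm2. The same tumours were low for Slc37a1, H2-M2 and Glo1, and the same for Pced1b and Arsa. The low tumours of Ceacam2 and of Ifitm2 were not the same. Sharing a chromosome does not place a pair within 20 Mb, and the distances of these pairs are not given here. These correlations are across genes, which are not independent replicates.

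**Figure D4:**
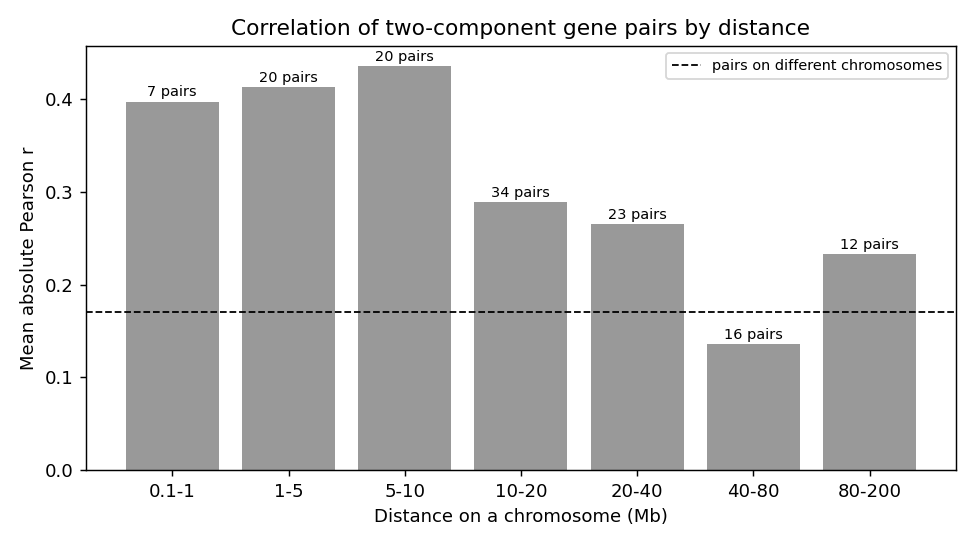
Mean absolute Pearson r (y axis, starting at 0) of pairs among the 62 genes with 2-component values, by distance on a chromosome in Mb (x axis), with the number of pairs above each bar; the dashed line marks the 1751 pairs on different chromosomes (0.170). Bars up to 10 Mb lie between 0.397 and 0.435, the bar at 40 to 80 Mb lies at 0.136 and that at 80 to 200 Mb at 0.233.

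Among the genes set in advance for every comparison, Tpx2, a spindle assembly factor, averaged 24.8 ± 5.98 RPKM (SD), Sipa1, a Rap1 GTPase-activating protein, 13.7 ± 2.31 RPKM and Rrp1b 9.84 ± 1.82 RPKM. Rrp1b rose with the proliferation score (0.17 ± 0.03 log2 units per SD, SE, adjusted p = 0.000811, limma) and fell with the stroma score (-0.16 ± 0.04, adjusted p = 0.00159). Tpx2, a member of the proliferation list, rose with the other members (0.31 ± 0.02, adjusted p = 2.06e-12, limma) and fell with the stroma score (-0.18 ± 0.05, adjusted p = 0.00929). Sipa1 and Xist passed with none of the 4 scores nor with insert size in limma; the smallest adjusted p of these was 0.0984, for Sipa1 with proliferation. Xist, the RNA that silences 1 X chromosome in female cells, averaged 67.9 ± 23.5 RPKM. It was 0.792 RPKM in animal 3427 and between 35.3 and 122 RPKM in the other tumours.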

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

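The depth class as a covariate or subset, removal of depth class or insert size from 2-component genes, the median over a gene's transcripts and the inclusion of small RNA genes were chosen after the data had been seen. Of named genes, correlations and list coherences under the alternatives run for each, no passing value changed its direction. Fits within a depth class were not counted among these for correlations and coherences. Within the deep libraries r of the adipocyte and skeletal muscle scores was -0.153, against 0.568 over all tumours. For coherence 121 of 122 values kept their side of the threshold, for list correlations 162 of 175 (the other 13 no longer passed), and for proximity of 2-component genes 7 of 7. Of values of named 2-component genes 9 of 55 no longer passed. Of values of named genes 11 of 1170 no longer passed for proliferation, 9 of 1174 for stroma, 48 of 1166 for T cell, 52 of 1174 for milk and 17 of 612 for insert size. A further 1 for proliferation, 36 for T cell and 51 for insert size passed only in an alternative, and 5 for proliferation, 11 for stroma, 5 for T cell, 25 for milk and 13 for insert size changed sign without passing. The stroma count stayed within 1.5 times of 2841 in every alternative except the depth classes, and the counts of correlated pairs and coherent lists did so in every alternative run. Within the deep libraries, 250 genes passed for proliferation, 660 for stroma, 20 for T cell, 4 for milk and 16 for insert size; within the shallow libraries 447, 1497, 112, 26 and 2. Fewer tumours entered these fits. Without the 2 farthest tumours 924 genes passed for proliferation, 306 for T cell, 51 for milk and 134 for insert size. The T cell count was 646 without the filter, where more genes were tested, 100 after quantile normalization and 412 with ranks. The insert size count was 11 with a pseudocount of 0.1, 11 without the filter, 3 with a mean of at least 5, 13 after quantile normalization, 22 with the library total, 468 with the depth class and 11 with small RNA genes. Variable genes numbered 494 with a pseudocount of 0.1 and 155 with the median absolute deviation. The 2-component genes numbered 25 with a mean of at least 5, 21 after removal of insert size, 26 after removal of depth class, 313 with a smaller component of at least 10% and 38 at 35%, which follow from the share required. For the other changes the cause was not tested. Leaving out each tumour in turn gave 1200 (without animal 4036) to 2744 genes for proliferation, 2256 to 3028 for stroma, 159 to 248 for T cell, 76 (without 4378) to 326 (without 4150) for milk, 1 (without 3871) to 113 (without 4438) for insert size, and 229 to 252 variable genes. Quantile normalization turned the milk split of 65 rising and 86 falling into 94 and 39.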

Other observations

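The tests of the orders of each score, of Xist, of the depth class behind T and B cell scores, and of shared reads, depth class and lost reads behind 2-component genes were chosen after the results had been seen; those of lymph node, salivary gland, GC content and the splits of depth classes were set down before theirs.

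Single tumours stood out for genes of other tissues. In the tumour of animal 4459 the saliva proteins Bpifa2 (18732 RPKM, 2.93 in the next tumour) and Smr3a (5483 RPKM, 13.2 in the next) were highest. So were the amylase Amy1 (4274 RPKM, 15.4 in the next) and Dcpp1 (1012 RPKM, 94.4 in the next). In the tumour of animal 4461, Scgb1b27 (2739 RPKM, 446 in the next tumour), Prol1 (2212 RPKM, 17.3 in the next) and the kallikrein Klk1 (404 RPKM, 101 in the next) were highest, where Bpifa2 was 0.062 RPKM. Car6 (795 RPKM) and Pip (792 RPKM) were highest there too, but reached 743 and 712 RPKM in the next tumour of each. Of 11 salivary gland genes 4 were highest in animal 4461, between the bounds set for and against salivary tissue in that piece. Most of the others, namely Amy1, Bpifa2, Smr3a, Dcpp1, Dcpp2 (404 RPKM) and Lpo (26.8 RPKM), were highest in animal 4459, and Aqp5 in animal 3427. A gene highest in another tumour could not count for animal 4461 whatever its value there, so the count cannot decide on salivary tissue in that piece. Salivary tissue in the tumour of animal 4459 is a candidate source of its high values, but no bound was set for it, so it was not tested. That tumour also had the highest proliferation score (1.99 SD). Keratinised epithelium scores were highest in animal 4438 (3.08 SD), which also had the highest hypoxia score (3.07) and the lowest stroma score (-2.53). Animal 4488 had nearly the same mean standardised value of keratinised genes (2.974 against 2.978), but -0.216 for hypoxia and 0.493 for stroma genes. The keratinised and hypoxia scores did not pass as a pair (r = 0.425, permutation p = 0.0233, adjusted p = 0.108), with r = 0.133 without animal 4438. Sprr1a, a protein of the cornified envelope, reached 110 RPKM in animal 4488 against a median of 0.795 RPKM. Luminal epithelial and immediate early scores rose together (r = 0.661, permutation p = 7e-05, adjusted p = 0.000919; rho = 0.699, p = 6e-05, adjusted p = 0.00157; 0.642 without animals 3871 and 4036, 0.775 deep, 0.376 shallow).

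Deep and shallow libraries differed in 169 genes in limma with Benjamini-Hochberg adjustment, 3 higher and 166 lower in the deep ones; 1 of 100 splits of the tumours, the real one, gave as many, and the highest other gave 86. Among the genes with the smallest p were Pde4c (-0.97 ± 0.09 log2 units, SE), Tmem95 (-1.31 ± 0.13), Asic4 (-0.76 ± 0.08) and Acap1 (-1.25 ± 0.13), named after their values were seen. Median transcript GC was 5.82 percentage points higher in the called genes (56.8 against 51.0%), past the bound of 5 set beforehand for GC bias. Over all tested genes the difference between the classes did not follow GC (r across genes -0.035), a value weighed only after it was seen, and on both values GC bias cannot be told apart from other causes. Skeletal muscle (-0.93 SD, permutation p = 0.0081, adjusted p = 0.085) and erythroid scores (-0.94 SD, permutation p = 0.0073, adjusted p = 0.085) were lower in deep libraries without passing adjustment over 21 lists.

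Chance orders of the scores over the tumours were counted for each association. For proliferation 1 of 100 orders, the real one, gave 2084 genes, and the highest other gave 1. For stroma 1 of 100 gave 2841 and the highest other 521, and for insert size 1 of 100 gave 5 and the highest other 3. For the T cell score 3 of 100 orders gave 202 or more, with 474 the highest other, and for the milk score 2 of 100 gave 151 or more, with 694 the highest other. In each case the share of orders that reached the real count was below 0.05, which does not by itself exclude chance. The list scores were made from the same expression values as the genes tested, so any list whose members vary together brings associated genes. The insert size count also ran from 1 to 113 when single tumours were left out. Why 1 order of the milk score gave 694 genes, several times the real count, was not tested.

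The tumour of animal 3427 had 0.792 RPKM of Xist, 1.11% of the median of the other tumours. A male animal is argued against, since 4 Y-linked genes summed to 0.091 RPKM. A candidate explanation is that a second X was missing from the whole tissue: Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation, lay a median of -0.52 log2 units from the other tumours, just past the bound of -0.5, from -0.80 (Kdm6a, the lowest of all tumours) to -0.29 (Ddx3x). Loss of the X in the tumour cells alone stays open: the test took 10% of the usual Xist as the least that other cells would leave, but the share of such cells was not measured. The stroma score of this tumour (0.48 SD, median 0.10) and the mean standardised values of its endothelial (0.603) and macrophage genes (0.745) were not low, which goes against a piece nearly free of other cells, but these values are relative to the other tumours. Loss in most of the piece would lower the escape genes too. A fault of the Xist locus itself was not tested.

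The correlation of neighbouring 2-component genes may reflect inherited segments, which the labels' design (a backcross) offers but which was not tested, since no genotypes were analysed here. Reads shared between related genes less than 1 Mb apart are argued against as the only source. Pairs 1 to 20 Mb apart still had a mean absolute r of 0.3617, above the highest of 10000 reordered positions (0.265). The limit was set on distance and not on relatedness, so reads shared between related genes farther apart stay open. The depth class is argued against only for the 26 genes called again after its removal, 25 of them among the 62. Their difference was 0.5101 (11 pairs), which cannot be set against that of all 62 because the genes were selected anew. For the rest of the 62 genes, which no longer passed, the part of the depth class was not tested. Loss of reads from the MOLF allele in mapping could lower a value by at most 1 log2 unit while the FVB copy is counted, and 29 genes had a gap above 1 by more than 2 SE; for the other 33 genes lost reads and a difference in expression cannot be told apart without reads per allele. Loss of FVB reads, which has no such bound, stays open for all of them.

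B cell genes rose with the T cell score, and lymph node tissue in some pieces is a candidate source. Of 5 genes listed for lymph node stroma with a mean of at least 1 RPKM, 3 rose with the score in limma, Cxcl13 (0.66 ± 0.13 log2 units per SD, SE), Ccl21a (0.61 ± 0.12) and Ltb (0.50 ± 0.05). Lymphocytes themselves make Ltb, so its rise does not bear on lymph node tissue. Madcam1 (0.17 ± 0.06, adjusted p = 0.201) and Lyve1 (0.17 ± 0.12, adjusted p = 0.567) did not pass, and the mean of the most abundant, Ltb, was 8.43 RPKM. The depth class is argued against, since the lower of the r within the classes was 0.829. Lymphocytes gathered within the tumours stay open as another source, since no test separated the 2.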
